A study of Homo sapiens with 2 samples.

How the data were processed

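RNA from MM.1S cells cultured with pDCs and from MM.1S cells cultured alone was labelled with biotin and hybridised to Affymetrix HG-U133 Plus 2.0 arrays, 1 array per group, per the labels' protocols. Groups were taken from the sample titles. The deposited values are linear intensity signals, 1 per probe set, made with MAS5, per the submitters' processing notes. The MAS5 version, the background step and detection calls are not given in the sources used here. From the values, both arrays share a scale: the mean after trimming 2% of probe sets at each end was 500.1 on both arrays. Such scaling sets the average signal of the arrays equal, so a change common to most transcripts would not be visible. All comparisons were made within this table and start from the values as deposited.

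Probe sets were named through the array platform's annotation, with symbols checked by gene identifier against RefSeq genes of the human assembly GRCh38.p14. Of 54675 probe sets, 41091 had 1 gene symbol, 1801 had several, 11721 had none and 62 were controls. Of those with 1 symbol, 41037 matched a RefSeq gene and 0 symbols needed an update. Only probe sets with 1 symbol were used for genes. Each gene was represented by the probe set with the highest mean log2 signal over both arrays, which gave 19775 genes. Members of a list without such a probe set were not analysed here.

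With no detection calls in use, the median signal of each array served as a floor (115.9 in co-culture and 124.0 alone), and lower signals were set to it. Of 27 bacterial control probe sets, chosen by the names Bs, Dap, Lys, Phe, Thr and Trpn, 0 were above the floor in co-culture and 2 alone. The log2 ratio is co-culture minus alone. A gene below the floor on 1 array has only a bound, written "at least", and a gene below it on both arrays has no ratio. Genes above the floor numbered 12913 in co-culture and 13017 alone. A difference of 2-fold was used as a threshold of size, since 1 array per group allows no test, no p-value and no standard error. For arrays, their number limits the precision.

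The gene lists, the marker lists, the threshold, the floor, the list comparison, the rule for named genes and all alternatives for these lists except 1 were set before the data were examined. For each of 35 lists, the median log2 ratio was placed as a percentile among 10000 random lists of the same size, matched on mean log2 signal in 20 bins. A list was called apart from other genes in the top 2.5% or the bottom 2.5% of random lists, a description of these arrays and not a p-value. By this rule 4 lists were higher, 6 were lower and 25 were within the range. Overlapping membership was kept.

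Named genes were chosen by a rule with 3 parts. The first took the 14 genes with the largest positive and the 14 with the largest negative ratio, among genes past 2-fold whose brighter signal was above the 75th percentile of that array and whose other probe sets above the floor were not past 2-fold the opposite way. The next took up to 4 members of each list with the largest ratios past 2-fold or, where there were none, the 2 members with the highest signal. The last always took CLEC4C, LILRA4, IL3RA and NRP1 for pDCs, SDC1, CD38, IRF4 and XBP1 for plasma cells, and ACTB and GAPDH. Genes outside the rule are said to be named after their values were seen.

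Alternatives were median centring of the log2 ratios, quantile normalization, a loess fit of the ratio on signal (span 0.3), floors at the 30th and 70th percentile or none, the mean over all probe sets of a gene, and leaving out probe sets of the x_at and s_at classes, which can bind several transcripts. Others were thresholds of 1.5-fold and 3-fold, unmatched random lists, lists without pDC markers, and a stricter set for the comparison of probe sets. Random lists matched on signal and on gene span (5 bins) were added after seeing the data, as were the FOXO, glucocorticoid and ATF4 lists of the closing section and the runs of these alternatives on them. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

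The calculations were tested on simulated data for a pair of arrays with 19775 genes and a noise SD of 0.25 (log2) per array. With 4-fold changes set in bright genes, 100 of 100 raised and 100 of 100 lowered genes passed 2-fold, as did 52 of 19575 unchanged genes. Of 200 unchanged lists of 25 genes, 8 fell outside the range of random lists, and 50 of 50 lists shifted by 0.5 (log2) were called higher. The simulated noise was not set from these arrays, whose log2 ratios had an SD of 0.527 over genes above the floor on both arrays. These counts check the calculation and give no error rate for the real arrays.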

Results

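Total RNA of MM.1S cells, a human multiple myeloma line grown as plasma-cell-like tumour cells, was measured on Affymetrix HG-U133 Plus 2.0 arrays. One group held MM.1S cells cultured together with plasmacytoid dendritic cells (pDCs), the dendritic cell type known for making type I interferon, and the other held MM.1S cells cultured alone. Each group had 1 array, so no value below has a replicate error (n = 1 per group) and the number of arrays limits the precision of every comparison. Each array gave signals for 54675 probe sets. The median signal was 115.9 on the co-culture array and 124.0 on the MM.1S-alone array, and the 75th percentile was 401.1 and 397.6. The 27 chosen control probe sets for bacterial transcripts had a median signal of 19.3 in co-culture and 24.8 alone, with highest signals of 71.2 and 147.2. ACTB control probe sets differed along the transcript: the ratio of the 3' to the 5' signal was 8.09 in co-culture and 19.5 alone, while for GAPDH it was 2.46 and 3.07. Whether pDCs were separated from the MM.1S cells before RNA extraction is not given in the sources used here.

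The comparison asks how transcript levels of myeloma cells differ when pDCs are present, a setting that the series links to tumour growth and to resistance against drugs. Proliferation genes, interferon-stimulated genes and adhesion receptors such as CD44 and ITGA4 were higher in co-culture. NF-kB targets, plasma cell genes, HLA class II genes and STAT3 and STAT5 targets were lower. Only proliferation genes, adhesion receptors and plasma cell genes stood apart from random lists in every alternative of the processing. T cell markers were also called higher, and survival genes and monocyte markers lower, but not in every alternative. Of 19775 genes, 14408 had a signal above the floor on at least 1 array, and 11522 had one on both. Among the 14408, 456 genes (3.16%) were at least 2-fold higher in co-culture and 650 (4.51%) were at least 2-fold lower. At 4-fold or more, 14 genes were higher and 25 were lower. Log2 signals of the genes above the floor on both arrays correlated with Pearson r = 0.961 across genes, which are not independent replicates. No test was possible with 1 array per group, so "higher" and "lower" describe these arrays.

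Genes with the largest ratios on the co-culture side included MACROD2, which removes ADP-ribose from proteins, with a signal of 1043 against 136 alone (7.66-fold). DSP, which encodes the desmosome protein desmoplakin, was 5.18-fold higher (667 against 129). TRIM65 was at least 5.30-fold higher, BMP8A at least 4.43-fold, ITGB8 at least 4.12-fold and GRHL3 at least 4.02-fold, each with a signal below the floor on the MM.1S-alone array. EMID1 was 4.54-fold higher and TMEM200A 4.44-fold higher. IGFBP7, a secreted protein that binds insulin-like growth factors, was 4.42-fold higher, and its other probe set above the floor in co-culture had a log2 ratio of at least 2.17. ZNF521, a zinc finger regulator of haematopoietic and B-lineage cells, was 4.27-fold higher, with 2.33 on its other probe set. The probe set annotated to MIR146A, which does not measure the mature microRNA, was 4.26-fold higher. MORC1 was 4.23-fold higher. GPRC5D, a surface receptor of plasma cells, reached 4255 against 1016 (4.19-fold). TEX9 was 4.12-fold higher, but its 2 other probe sets above the floor gave log2 ratios of -0.25 and 0.43. All other probe sets of TRIM65, BMP8A, EMID1 and MIR146A were below the floor on both arrays, so each of these ratios rests on 1 probe set.

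On the lower side, DEPP1, a stress and fasting-response gene controlled by FOXO factors, had a signal of 103 in co-culture against 1969 alone and was at least 17.0-fold lower on its brightest probe set. The other DEPP1 probe set, at 157 against 235, had a log2 ratio of only -0.59. HLA-DQA1 was at least 11.9-fold lower (20.3 against 1376). SLC2A5, the fructose transporter GLUT5, had 619 against 6193 (log2 ratio -3.32), with -0.21 on another probe set and -1.93 or lower on one that was below the floor in co-culture. DNAAF1, which acts in the assembly of ciliary dynein, was 8.21-fold lower. PPBP, a platelet chemokine, was at least 8.26-fold lower, CXCL5, a neutrophil-attracting chemokine, at least 6.34-fold, and LYZ, the lysozyme gene of myeloid cells, at least 6.14-fold. GDF15, a stress-induced cytokine, was at least 5.86-fold lower, with -0.19 on its other probe set. VAT1 was at least 6.87-fold lower, H1-3 at least 5.28-fold and GNAL at least 4.94-fold. IFFO2 was 6.38-fold lower and TEX19 5.79-fold lower. GBP2, an interferon-inducible GTPase, was at least 6.93-fold lower on its brightest probe set and had a log2 ratio of 0.06 on the other. All other probe sets of HLA-DQA1, DNAAF1, CXCL5, LYZ and GNAL were below the floor on both arrays, also in MM.1S cells alone, so each of these ratios rests on 1 probe set.

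**Figure D1:**
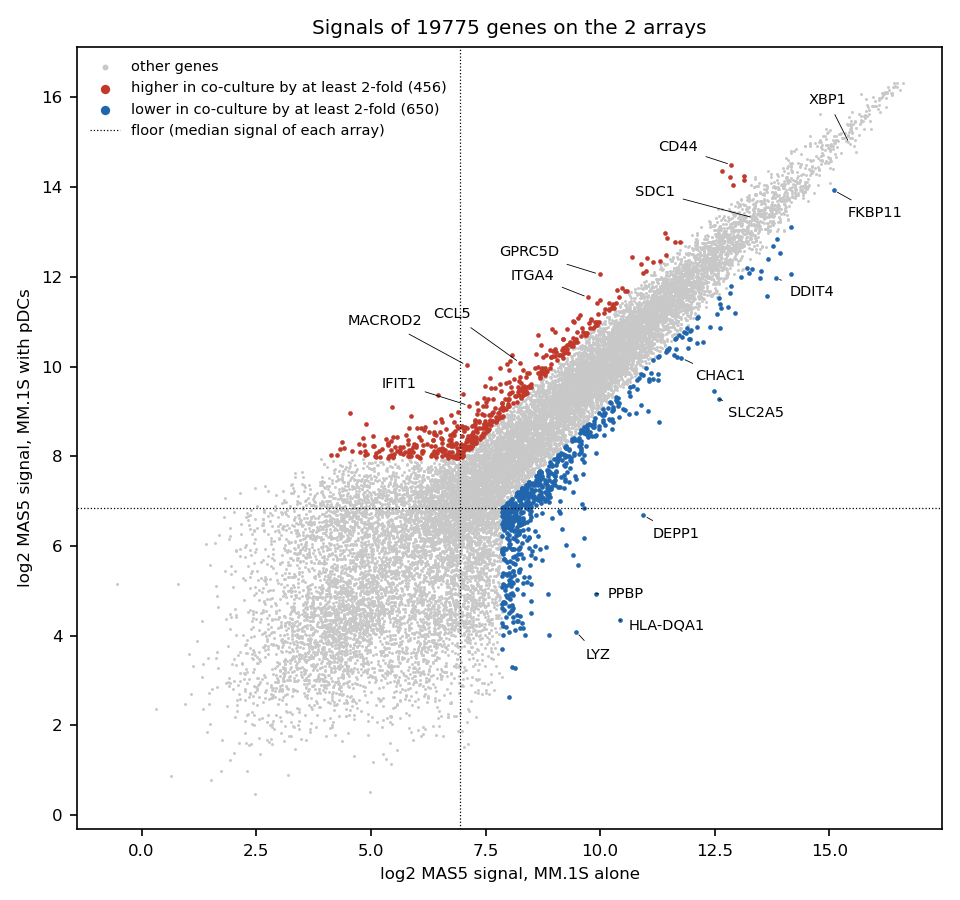
Log2 MAS5 signal of 19775 genes, with MM.1S alone on the x axis and MM.1S with pDCs on the y axis; each point is 1 gene on 1 array per group, and dotted lines mark the floor of each array. The 456 genes in red were at least 2-fold higher in co-culture and the 650 in blue at least 2-fold lower, with SDC1 and XBP1 inside the grey band.

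Proliferation genes were higher in co-culture as a group. Of 36 measured members, 31 had a positive ratio and 5 a negative one, and the median log2 ratio was 0.31, at percentile 100 of 10000 random lists matched on signal. CENPE, a kinesin of the kinetochore, was the only member past 2-fold (2.02-fold, 1660.1 against 822). Several mitotic genes, named after their values were seen, followed closely. CENPF had a signal of 5035 against 2525. Log2 ratios were 0.91 for the spindle checkpoint kinase TTK, 0.86 for CCNB2, 0.78 for TOP2A and 0.71 for the proliferation marker MKI67. In the 22 members with at least 2 probe sets above the floor on both arrays, the median of each gene's lowest ratio was 0.04. It was -0.24 in genes matched on signal but not on the number of probe sets, and 10 of the 22 were below 0. CENPE was just under 2-fold after quantile normalization and after loess.

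Interferon-stimulated genes were mixed but higher as a group, with 22 of 36 measured members positive, 14 negative and a median log2 ratio of 0.29 (percentile 99.9). IFIT1, an antiviral RNA-binding protein, was 3.96-fold higher (560 against 141), SAMD9 2.32-fold and IFI6 at least 2.23-fold. No member was 2-fold lower. Members on the other side, named after their values were seen, included ISG20 at -0.83, CXCL10 at -0.75 and ISG15 at -0.41. The group did not stand apart when all probe sets of a gene were averaged (median 0.029, percentile 73.2).

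Adhesion and homing receptors were higher as a group, with 18 of 28 measured members positive and a median log2 ratio of 0.21 (percentile 99.1). CD44, a hyaluronan receptor, was 3.10-fold higher (23107 against 7447), and 7 of its 8 other probe sets above the floor were also past 2-fold in this direction; the remaining one, below the floor in co-culture, had -1.06 or lower. ITGA4, the alpha chain of the VLA-4 integrin that binds VCAM1, was 3.49-fold higher (2979 against 854), with log2 ratios from 0.40 to 0.84 on its 3 other probe sets. The chemokine receptor CCR10 was 2.45-fold higher. ICAM1 was 2.15-fold lower (1325 against 2846) and was the only member past 2-fold on that side.

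**Figure D2:**
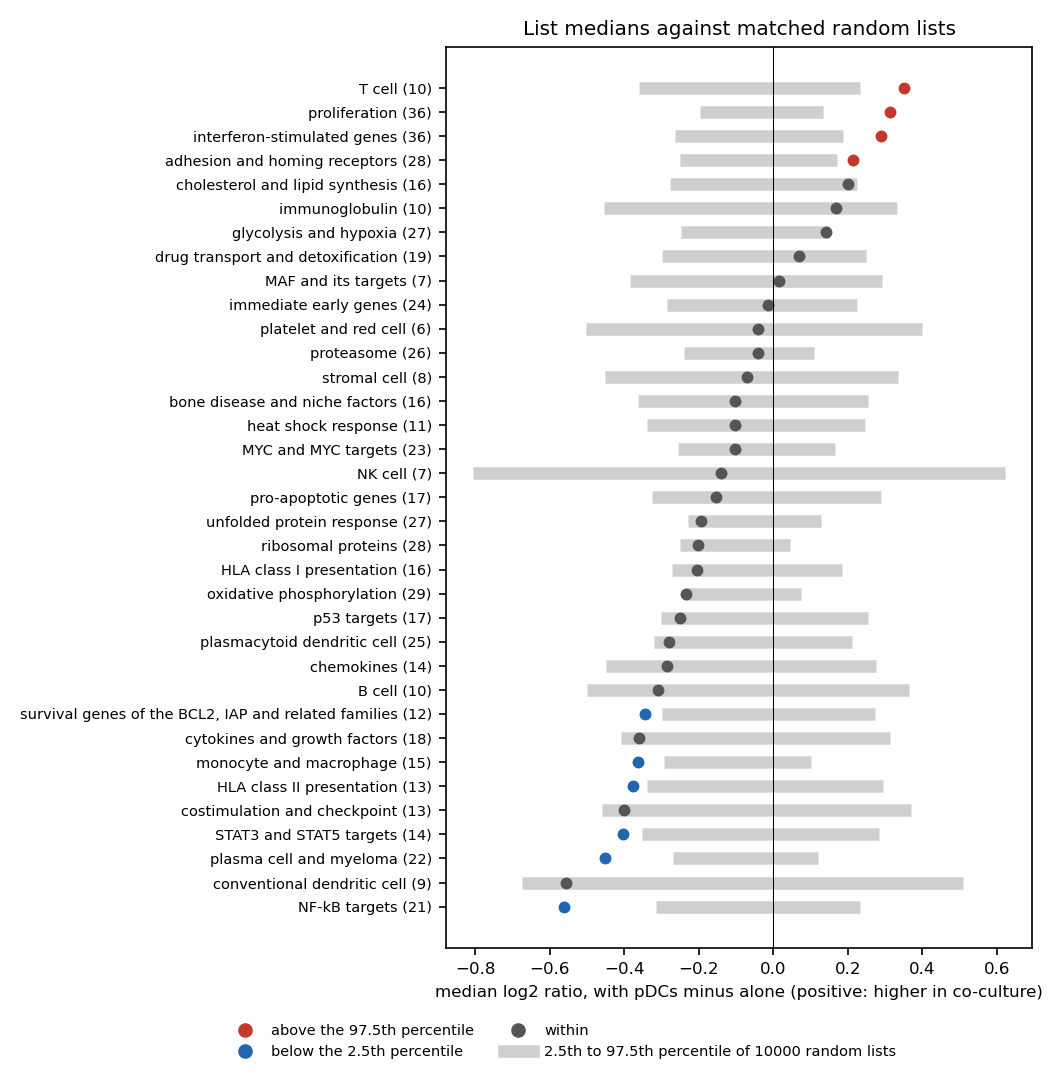
Median log2 ratio (x axis, co-culture minus alone) of each of the 35 gene and marker lists, with the number of measured members in parentheses and grey bars for the central range of 10000 random lists matched on signal. Red points (4 lists) lie above that range, blue points (6 lists) below it and grey points (25 lists) within it.

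NF-kB targets were lower as a group. The median log2 ratio of 21 measured members was -0.56, at percentile 0 of the random lists, while the mean was -0.30, as 13 members were negative and 8 positive. ICAM1 was 2.15-fold lower, and CFLAR, an inhibitor of caspase-8, was 2.11-fold lower (2939.8 against 6206). NFKB1, which encodes the p105/p50 subunit, went the other way and was 2.13-fold higher (2491 against 1172). Of members named after their values were seen, the inhibitor gene NFKBIA had -0.76, while TNFAIP3 had 0.32 and GADD45B 0.94. Averaging all probe sets of a gene gave a median of -0.22 at percentile 6.38, which no longer stood apart. In the 9 members with at least 2 probe sets above the floor on both arrays, the median of each gene's highest ratio was 0.06, against 0.31 in genes matched on signal only.

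Survival genes of the BCL2, IAP and related families had a median log2 ratio of -0.35 over 12 measured members (percentile 1.13), with 7 negative and 5 positive. CFLAR was the only one past 2-fold, and 9 of its 10 other probe sets above the floor were negative without reaching 2-fold. Of members named after their values were seen, MCL1 had -0.86 and BCL2L1 -0.47, while BCL2 had 0.94 and BIRC5 0.45. The group's median moved to -0.22 (percentile 9.07) with a lower floor. STAT3 and STAT5 targets had a median of -0.40 over 14 measured members (percentile 1.25), with 11 negative, but did not stand apart with a lower floor (-0.33, percentile 3.41) or with none (percentile 3.56). BCL6, a transcriptional repressor, was at least 4.85-fold lower, STAT3 2.76-fold lower (1179.9 against 3256) and CISH 2.04-fold lower. The other BCL6 probe sets, at 19.3 against 88.1 and 7.27 against 15.7, were below the floor on both arrays. SOCS2 was 2.68-fold higher, with a log2 ratio of 0.93 on another probe set and -0.20 or lower on one that was below the floor in co-culture. One of the 3 other STAT3 probe sets had a log2 ratio of 0.26.

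Plasma cell and myeloma genes were lower as a group, with 16 of 22 measured members negative and a median log2 ratio of -0.45 (percentile 0.01). FKBP11, a prolyl isomerase of the secretory pathway, was 2.24-fold lower (15633 against 34961). XBP1, the transcription factor of secretory cells, had -0.48, and CD38 had -0.67. SDC1 and IRF4 differed little, at -0.05 and 0.07. GPRC5D was the only member more than 2-fold higher. HLA class II genes were lower as well: 12 of 13 measured members were negative, with a median of -0.38 (percentile 1.72). The group did not stand apart from unmatched random lists (percentile 3.32) or from lists matched on signal and gene span (percentile 4.53). HLA-DQA1 was the lowest, HLA-DPA1 was 2.88-fold lower (4002 against 11528), HLA-DPB1 2.11-fold and HLA-DRB1 2.07-fold. Probe sets for HLA genes can also bind transcripts of related HLA genes, so single members are uncertain. Monocyte and macrophage markers were lower on the same array, with LYZ at 17.0 against 711.

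**Figure D3:**
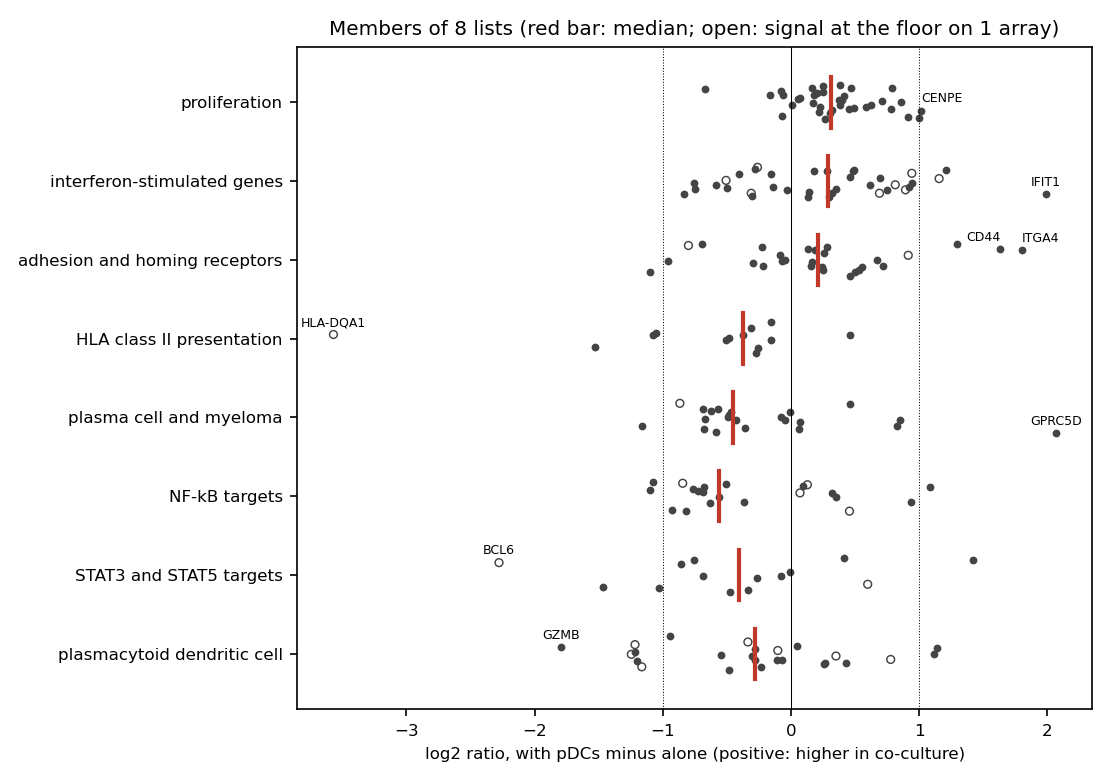
Log2 ratio (x axis, co-culture minus alone) of each measured member of 8 lists; each point is 1 gene, open points had a signal at the floor on 1 array, red bars are list medians and dotted lines mark 2-fold. Medians lie at 0.31 for proliferation, -0.56 for NF-kB targets and -0.28 for pDC markers.

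Among cytokines and growth factors, 18 members were measured and the median log2 ratio was -0.36 (percentile 4.83). HGF was 2.63-fold lower (249.8 against 658), and all 3 of its other probe sets above the floor were past 2-fold the same way. IL13 was at least 2.77-fold lower. DKK1, a WNT antagonist made by myeloma cells in bone disease, was at least 3.19-fold higher. TGFB1 was at least 2.51-fold higher, but the other TGFB1 probe set had -0.29 or lower (40.5 against 142). Chemokines had a median of -0.28 over 14 members (percentile 16.8). CCL5 was 3.55-fold higher (1083 against 305), with both other probe sets also past 2-fold. CCL18 was 3.25-fold lower and CXCL13 at least 2.24-fold lower. In the list of bone disease and niche factors (16 measured, median -0.10, percentile 39.3), MMP9 was 3.05-fold lower and JAG2 at least 2.10-fold lower. MAF and its targets had a median of 0.01 over 7 members (percentile 69.2), and ITGB7 and CCND2 had log2 ratios of 0.17 and -0.08.

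The lists in this paragraph, tied to drug response, were not apart from other genes, except the unfolded protein response under 1 alternative. Survival genes, given above and also tied to drug response, were called lower (percentile 1.13), though not under every alternative. Drug transport and detoxification genes had a median log2 ratio of 0.07 over 19 measured members (percentile 73.6), which turned to -0.11 with a lower floor or none and to -0.10 with the mean over probe sets. HMOX1, the heme oxygenase of the oxidative stress response, was 2.15-fold higher, and the exporter ABCC1 was 2.00-fold lower. The exporter ABCC4 was 2.06-fold higher on its brightest probe set, while its 3 other probe sets, each below the floor on 1 array, had signals of 151 against 64.4, 118 against 49.6 and 8.58 against 125. Proteasome genes had a median of -0.04 (26 members, percentile 65.6), with PSMB4 at 0.35 and PSMA1 at -0.15. Heat shock genes had -0.10 (11 members, percentile 41.2), with HSPD1 at -0.10 and HSP90AA1 at -0.57 on their brightest probe sets. The 3 other HSP90AA1 probe sets were positive, and the next brightest of HSPD1 had 0.78. The unfolded protein response had -0.19 (27 members, percentile 6.99; -0.21 and percentile 1.66 with the mean over probe sets), and CHAC1, a glutathione-degrading enzyme induced by ATF4, was 2.98-fold lower (1169 against 3487). Pro-apoptotic genes had -0.15 (17 members, percentile 20.2). TNFSF10, which encodes TRAIL, was 2.60-fold higher. BAX was 3.11-fold lower on its brightest probe set but had 0.16 on the other. Targets of p53 had -0.25 (17 members, percentile 5.83), with the cell cycle inhibitor CDKN1A 2.55-fold lower (1559 against 3977) and SESN1 2.01-fold higher, or just under 2-fold after quantile normalization and after loess.

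Metabolic groups lay within the range of random lists matched on signal, though not under each alternative. Glycolysis and hypoxia genes had a median log2 ratio of 0.14 over 27 measured members (percentile 97.0), and percentile 98.7 when random lists were matched on gene span too. DDIT4, an inhibitor of mTORC1 induced by stress, was 3.62-fold lower (4022 against 14545), ANKRD37 2.04-fold lower and HK1 2.26-fold higher. Cholesterol and lipid synthesis genes had 0.20 (16 members, percentile 96.0), with SCD at 0.57 and FDPS at 0.02. Oxidative phosphorylation genes had -0.23 (29 members, percentile 2.92; 2.31 with a lower floor and 2.36 with none), with COX7C at -0.23 and COX7A2 at -0.20. Ribosomal protein genes had -0.20 (28 members, percentile 10.2), with RPS27 at -0.36 and RPS23 at -0.27 on its brightest probe set and 0.30 on the other. All 28 were negative as deposited, but 8 were positive after loess. MYC and its targets had -0.10 (23 members, percentile 33.5), with HSPD1 at -0.10 and NPM1 at -0.01. NPM1 turned positive under each other scaling, and HSPD1 after quantile normalization, after loess and with the mean over probe sets. Immediate early genes had -0.02 (24 members, percentile 56.1), a median that turned positive under each other scaling. Their member DUSP1, a MAP kinase phosphatase, was 2.99-fold lower and KLF2 was 2.01-fold lower.

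Among immune surface genes, HLA class I genes had a median of -0.20 (16 members, percentile 9.87), with HLA-C at -0.39 and B2M at -0.15. Costimulation and checkpoint genes had -0.40 (13 members, percentile 4.53), with CD70 2.54-fold lower and VSIR 2.18-fold lower.

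Markers of pDCs were not higher on the co-culture array. CLEC4C (BDCA-2) and IL3RA (CD123) had signals below the floor on both arrays, 61.4 against 6.43 for CLEC4C and 29.0 against 21.1 for IL3RA. LILRA4 had a log2 ratio of 0.26 (306 against 256), and NRP1 was below the floor in co-culture (35.0 against 146). Over 25 measured pDC markers, of which 23 were above the floor in MM.1S cells alone, the median was -0.28 (percentile 5.46). GZMB was 3.47-fold lower (174 against 604), MAP1A at least 2.37-fold, BCL11A at least 2.32-fold and PACSIN1 2.32-fold lower. Of 2 other BCL11A probe sets, each below the floor on 1 array, the log2 ratio was -0.47 or lower on one and at least 0.20 on the other. LAMP5 and RUNX2, named after their values were seen, had log2 ratios of 1.11 and 1.14 and were also high in MM.1S cells alone.

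Markers of other cell types gave no common direction. Monocyte and macrophage markers had a median log2 ratio of -0.36 over 15 measured members (percentile 0.5), of which 7 were above the floor in co-culture and 12 alone. LYZ was the only one past 2-fold, though ratios of members below the floor on 1 array are only bounds. With a floor at the 30th percentile the median was -0.65 over 19 members (percentile 3.95). With a floor at the 70th percentile the list held 3 members with a median of -0.26 (percentile 29.2). T cell markers had a median of 0.35 over 10 members (percentile 99.6), 8 of them above the floor in MM.1S cells alone. TRAT1 was 2.01-fold higher and CD6 at least 2.02-fold lower, and the median was 0.13 (percentile 77.4) with a lower floor. B cell markers had -0.31 (10 members, percentile 13.0), with FCRLA 2.85-fold lower (1885 against 5379) and both of its other probe sets past 2-fold the same way. Conventional dendritic cell markers had -0.56 (9 members, percentile 7.26), with XCR1 at least 2.04-fold higher and CD1E 2.03-fold lower. Immunoglobulin genes had 0.17 (10 members, percentile 88.9), with IGHM at least 2.52-fold higher on its brightest probe set and 3 others with only bounds, -0.78 or lower on one and at least 0.17 and 0.50 on the rest. NK cell markers had -0.14 (7 members, percentile 45.2), with PRF1 2.41-fold higher. Platelet and red cell markers had -0.04 (6 members, percentile 53.6), and stromal cell markers -0.07 (8 members, percentile 48.3), with FN1 at 0.87 and COL1A1 at -0.41. The housekeeping genes ACTB and GAPDH had log2 ratios of 0.37 and 0.00.

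Other probe sets of the same gene are the only repeat measurement on these arrays, and they share the RNA. Of the higher genes, 194 had another probe set above the floor, of which 119 (61.3%) had the same sign and 31 (16.0%) were also past 2-fold. Of the lower genes, 254 had one, of which 167 (65.7%) had the same sign and 46 (18.1%) were also past 2-fold. With both probe sets above the floor on both arrays, the same sign was seen in 71 of 101 higher genes (70.3%) and 89 of 129 lower genes (69.0%). Across 4844 genes with 2 probe sets above the floor on both arrays, the SD of the difference between both log2 ratios was 0.635 and their Pearson r was 0.290. The central range of log2 ratios ran from -0.997 to 0.837 for the dimmest genes above the floor on both arrays (signals of 121 to 194), from -1.48 to 1.22 at signals of 194 to 270 and from -0.83 to 0.69 for the brightest genes.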

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

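Both results given here come from checks chosen after the data were seen. Probe sets without a single gene symbol took no part in the gene comparison, and 55 of these 13522 had a signal above the 75th percentile and at least 2-fold above that of MM.1S cells alone, while 92 were at least 2-fold lower. The control probe set for the 5' end of ACTB, also outside the gene comparison, was 2.93-fold higher in co-culture, against 2.38-fold for the middle and 1.22-fold for the 3' end. The same positions of GAPDH differed by 1.42-fold, 1.28-fold and 1.14-fold.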

How the results depend on the processing

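Of the alternatives given here, only random lists matched on signal and gene span were added after the data were seen. No paired analysis was possible because each group had 1 array. Proliferation (medians 0.31 to 0.36), adhesion receptors (0.20 to 0.25) and plasma cell genes (-0.48 to -0.36) kept their direction and stayed apart from random lists in 10 of 10 alternatives each. Over all 35 lists, 305 of 350 alternatives left the reading as it was and 0 turned a list that stood apart, while 18 ended and 12 gained a standing apart and 15 turned the sign of a median inside the range. Some outcomes in these counts, also among the 10 of 10, were fixed in advance. Median centring shifts every ratio alike, so it cannot change a list's percentile. Unmatched random lists and those matched on gene span cannot change a list's median. NK cell markers had only 2 members above a floor at the 70th percentile and gave no value there. Counts of genes past 2-fold moved by less than 1.5 times under each scaling (higher 476 to 492, lower 588 to 596), but the floor sets them by construction: 1502 higher and 1920 lower at the 30th percentile, 187 and 199 at the 70th, and 2365 and 2776 with none. At 1.5-fold, 1656 were higher and 2208 lower, and at 3-fold 64 and 95. These lists no longer stood apart, and the cause was not tested. With the mean over probe sets: NF-kB targets -0.22 (percentile 6.38), interferon-stimulated genes 0.029 (73.2) and T cell markers 0.15 (89.4). With a floor at the 30th percentile: survival genes -0.22 (9.07), STAT3 and STAT5 targets -0.33 (3.41), monocyte markers -0.65 (3.95) and T cell markers 0.13 (77.4). With no floor: survival genes -0.22 (9.32), STAT3 and STAT5 targets -0.33 (3.56), monocyte markers -0.37 (17.2) and T cell markers 0.28 (89.0). With a floor at the 70th percentile, monocyte markers had -0.26 (29.2). Without x_at and s_at probe sets, survival genes had -0.28 (4.38) and monocyte markers -0.28 (3.41). Against unmatched random lists, medians stayed at -0.35 for survival genes (4.37), -0.38 for HLA class II (3.32) and -0.36 for monocyte markers (2.77). Matched on gene span, HLA class II stayed at -0.38 (4.53). Gained, as percentiles: cytokines 1.66 and chemokines 0.655 (5 members) with a floor at the 70th percentile, costimulation 1.80 with that floor and 1.73 without x_at and s_at probe sets; cytokines 1.68, costimulation 2.25 and conventional dendritic cell markers 0.99 against unmatched lists; the unfolded protein response 1.66 and B cell markers 2.3 with the mean over probe sets; oxidative phosphorylation 2.31 at the 30th percentile and 2.36 with no floor; and glycolysis and hypoxia 98.7 matched on gene span. Turned medians: drug transport -0.11 at the 30th percentile and with no floor and -0.10 with the mean over probe sets; heat shock 0.10 and NK cell markers 0.06 with that mean; stromal markers 0.16 and 0.08 with floors at the 30th and 70th percentile and 0.01 without x_at and s_at probe sets, where proteasome genes had 0.01 and bone disease factors 0.00; immediate early genes 0.01 to 0.04 under each scaling and with a lower floor or none. Of the named genes past 2-fold, TGFB1 alone turned direction, to -0.29 or lower without x_at and s_at probe sets, where its other probe set was read. Of 81 named genes past 2-fold, 74 stayed so under every scaling and 41 in every alternative that gave them a ratio. Signals near the floor limit the dim genes, where signals of the 27 chosen bacterial controls reached 147.2.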

Other observations

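The tests with random lists matched on gene span and the reading of pDC markers for exchanged labels were chosen after the results were seen, and the FOXO, glucocorticoid and ATF4 lists were drawn up after the named genes were seen but before the values of their members were, with their alternatives added later, as was the rule that such a list must be lower in every alternative to count for its programme. For the tests of 3' bias the limit of 6 genes from their first run was kept, though under a limit of 80% of members, weighed after the values were seen, both would be void, and the part on members without a test and the use of the ACTB control to set aside the test of NF-kB targets were also chosen after. The genes of the next paragraph were chosen after their values were seen.

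These are single genes, and no list of their pathways was tested. CYP26A1, which degrades retinoic acid, had 8028 against 2740.1 alone (2.93-fold). UGT2B17, which conjugates androgens, was 3.34-fold higher (5538 against 1656), and UGT2B15 was 3.03-fold higher with 0.74 and at least 0.27 (log2) on its 2 other probe sets; these related genes can share probe signal. PCP4, a calmodulin-binding peptide, was 3.22-fold higher (20931 against 6506). ASS1, which makes argininosuccinate, was 4.24-fold lower (4307 against 18274). SAT1, which acetylates spermine and spermidine for breakdown, was 4.19-fold lower, and both of its other probe sets were past 2-fold the same way (-2.94 and -1.81). PDE4B, a cyclic AMP phosphodiesterase, was 4.10-fold lower, with -1.18 and -0.38 or lower on its other probe sets.

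Proliferation genes were higher in co-culture, with a median log2 ratio of 0.31. Genes with a longer span had higher ratios in general (Spearman rho 0.154 across 11517 genes), yet among random lists matched on signal and span the list stayed at percentile 100, which argues against span as the whole cause. Stronger 3' bias of the RNA from MM.1S cells alone could raise ratios of probe sets far from the 3' end. In the 22 members with several probe sets, the median of each gene's lowest ratio was at percentile 99.8 of genes matched on signal. Of these 22 lowest ratios, 10 were below 0. The comparison was not matched on the number of probe sets, and a lowest ratio tends to fall as more are read. Positions of probe sets were not given in the sources used here. The test therefore does not decide, and such a bias stays open for these 22 and for the other 14 members, whose median was larger (0.38 against 0.24). Culture density or time of harvest stays open with 1 array per group, as does an effect of pDCs, the difference that the design names, and exchanged labels would turn the direction of this and every other difference. More cells in cycle in the presence of pDCs is a hypothesis that these arrays may only raise.

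NF-kB targets were lower in co-culture, with a median log2 ratio of -0.56, but this depends on the probe sets read: their mean gave -0.22 (percentile 6.38). The highest ratio per gene was above 0 in 6 of 9 members, but taking the highest raises a ratio by construction. Its median was 0.06, against 0.31 in genes matched on signal. Gene span as the whole cause is argued against by percentile 0 among lists matched on signal and span. The test of 3' bias is void (median highest ratio at percentile 7.81 in 9 of 21 members). The 5' control of ACTB was higher in co-culture, so such a bias would raise ratios away from the 3' end. With both arrays scaled to the same mean, it could also lower ratios near the 3' end, and positions of probe sets were not known. Such a bias stays open for this pattern. Exchanged labels cannot be told apart from a true difference, and pDC markers could not test them. Of 25 measured markers, 23 were above the floor in MM.1S cells alone, and CLEC4C and IL3RA were below it on both arrays. Whether pDCs were removed before RNA extraction is not known either, so the list's percentile of 5.46 decides nothing. Lower NF-kB output in MM.1S cells next to pDCs is therefore only a possible explanation, beside these.

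A few genes tied to stress or quiescence, picked for their low ratios and not as a fixed list, were lower. They were BCL6 (at least 4.85-fold, with its other probe sets below the floor on both arrays), DDIT4 (3.62-fold), CDKN1A (2.55-fold) and DEPP1 (at least 17.0-fold, but -0.59 in log2 on its other probe set). SESN1 and HMOX1 were higher, by just over 2-fold or just under it depending on the alternative. No technical explanation was tested for these genes themselves. With random lists matched on gene span too, percentiles were 0.115 for glucocorticoid, 2.83 for FOXO and 26.8 for ATF4 targets, the lists given next. Other glucocorticoid targets were lower as a list (15 measured, median -0.43, percentile 0.22), but not with the mean over probe sets (-0.16, percentile 17.1) or without x_at and s_at probe sets (-0.02, percentile 52.3), only RHOB was past 2-fold (-1.59) and 5 had positive ratios (ERRFI1 0.99, GLUL 0.34, FKBP5 0.22, NFIL3 0.20 and SLA 0.16), so weaker glucocorticoid signalling stays open. Other FOXO targets had a median of -0.26 over 22 measured members (percentile 2.64), just inside the range, with 9 positive and CCNG2 at 1.43. With the mean over probe sets these targets had -0.07 (percentile 28.6), and no alternative placed them below the range. TSC22D3 and TXNIP are in both the FOXO and the glucocorticoid list. Targets of ATF4 in the amino acid response had -0.08 (percentile 38.2), which decides nothing. Which programme, if any, links these genes stays open, and pDCs may act through none of them.

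Median log2 ratios of autosomes ran from -0.13 for chromosome 19 to 0.12 for chromosome 4. Over 5 bins of gene span, medians ran from -0.15 for the shortest genes to 0.09 for the longest. Stronger 3' bias on the MM.1S-alone array was not tested for the other lists, whether higher or lower in co-culture. Such a bias stays open for them, as for adhesion receptors and plasma cell genes.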
